A study of Mus musculus with 8 samples.

How the data were processed

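RNA was extracted from mouse corneas with Trizol and sequenced from a stranded RNA library kit, per the labels' protocols. The samples were 4 corneal samples given BAC and 4 given PBS, with groups and replicate numbers taken from the sample titles. HISAT2 2.1.0, StringTie 1.3.3 and the build GRCm38 are listed in the submitters' processing notes, with no role or order. The authors deposited FPKM (fragments scaled to transcript length and to the fragments sequenced) for 13437 genes and 25635 transcripts, all protein-coding per the file headers. Every gene kept by the authors had a mean FPKM of at least 0.501 in the higher group. The authors also deposited log2 changes, group means on a log2 scale, ratios (fold changes), p-values and q-values. Recomputed from the FPKM, the deposited log2 changes and means were those of log2(FPKM + 1), although the file headers call the means FPKM. The authors' p-values equalled, within 1%, those of an ordinary equal-variance test on the same scale, and were not used. Their lists held 3708 higher and 1599 lower genes, at an unadjusted p of 0.05 and a 1.5-fold change, and 5000 higher and 2381 lower transcripts. Of the authors' higher genes 3533 were kept by the filter used here, and all 3533 passed in the same direction; of their lower genes 1567 were kept and all 1567 passed.

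Of the gene identifiers 87.6% matched GENCODE M21 with their version, each with the same coordinates, and 99.8% matched without it. A symbol stood on more than 1 row for 13 symbols, and rows were kept apart by identifier. Depth is unknown. Between 17.0% and 49.7% of the 300 lowest values per library, in genes with 1 transcript, lay within 0.05 of a whole multiple of the best-fitting step, where 10% is chance for a step fixed beforehand. Whole reads could therefore not be recovered, no intervals are given, and an exact 0 is described as listed at 0. Genes listed at 0 numbered 56 to 84 per BAC library and 281 to 403 per PBS library. Folds printed are ratios of group mean FPKM, while log2 changes are on the log2(FPKM + 1) scale, which understates the change of genes with low values.

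The samples, the tests, the alternatives, the gene lists and the rule for naming genes were fixed before the data were examined. Genes with a mean FPKM of at least 0.5 over all 8 samples were tested with limma 3.58.1 in R 4.3.3, on log2(FPKM + 1), with group as the only term, a trended prior variance, two-sided tests and Benjamini-Hochberg adjustment over all genes kept. The threshold was an adjusted p of 0.05. Transcripts were tested in the same way. Gene lists with at least 5 measured members were tested with camera from limma, at a preset correlation between genes of 0.01 and, beside it, at an estimated correlation, and adjusted over the 40 lists tested. The lists covered mitochondrial, metabolic, inflammatory, epithelial, stromal and stress genes and markers of other cell types in or near the cornea, 43 in all. They describe bulk RNA and assign no cell to a type. A gene nearly absent from the PBS group passed the filters only where BAC raised it, so its direction was fixed beforehand. The share of summed FPKM from mtDNA-encoded mRNAs was compared with an exact permutation test over 70 assignments.

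The genes named were the 12 largest rises and the 12 largest falls among genes past the threshold, with no overlap between groups, a mean FPKM of at least 2 in the higher group and an established symbol. To these were added up to 4 members per list with the smallest adjusted p, and Tfam and Aim2, which the series title names. Other genes named are marked as chosen after their values were seen.

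On simulated FPKM tables with 200 changed rows, the gene test recovered 57% of changes of 0.5 log2 and 93% of changes of 1 log2, with 7 false calls among 12967 genes. For 23349 transcripts it recovered 7% and 45%, with 8 false calls. A shifted list was found in 20 of 20 simulated tables, with 3 calls of other lists over those tables. In all simulations genes varied independently of each other, and the 200 changed rows had a control mean above 1 on the log2 scale. In the data 67.6% of genes passed, and the estimated correlation within a list reached 0.883 (lens). The simulated rates therefore need not hold for these data. The alternatives were a pseudocount of 0.1, no filter, a filter at 2, rescaling every sample to one total, median-of-ratios scaling, quantile normalization, an untrended and a robust prior, weights per sample, a block for replicate number, a fold minimum, and each sample left out in turn. Count-based tests were planned only for a table of counts and were not run. Rescaling was done in R, and figures and checks used Python 3.11.15, scipy 1.17.1 and matplotlib 3.10.9.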

Results

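Gene expression was measured by RNA sequencing in corneas of C57BL/6 female mice, in a model of dry eye disease. Mice of the disease group received 5 µl of 0.2% BAC on both eyes, 2 times daily for 7 days, and control mice received PBS. There were 4 corneal samples per group, taken at day 7. The labels do not say how many animals or eyes went into a sample, so all p-values describe only the spread between these samples. The authors' tables held FPKM values for protein-coding genes, whose sum ran from 268629 to 283538 per sample; read depth is unknown. Across genes, libraries of the same group correlated with Pearson's r between 0.976 and 0.986.

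Corneas given BAC differed from control corneas in most of the genes measured. The 12 genes that rose furthest included the cytokine gene Il1b, the chemokine genes Ppbp and Cxcl5, the alarmin gene S100a8, the matrix genes Mmp13, Timp1 and Col3a1 and the cornified envelope genes Sprr2a1 and Sprr2a2. Of the 12 genes that fell furthest, 4 stood in the fixed list for corneal epithelium, namely Krt12, Lypd2, Slurp1 and Upk1b. Krt12, the keratin specific to corneal epithelium, was at 10.5 ± 2.98 FPKM (SD, n = 4) with BAC against 10325 ± 228 FPKM with PBS, which is 979-fold lower. Ppbp, a CXC chemokine precursor, was at 1213 ± 153 FPKM with BAC against 0.780 ± 0.711 FPKM with PBS.

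Of 12967 genes tested with limma, 8771 passed an adjusted p of 0.05, of which 5845 were higher and 2926 lower with BAC. At a log2 change of at least 1 there were 2134 higher and 822 lower genes, against 1776 and 1095 after median-of-ratios scaling and 1458 and 1282 after quantile normalization. The values of the groups did not overlap for 63.5% of genes, where chance gives 2.86%. The median of all genes lay 0.19 log2 above 0, and changes are printed with this shift included unless given relative to it. Higher genes made up 66.6% of the calls on the FPKM as deposited. After median-of-ratios scaling 4497 genes were higher and 4181 lower (51.8% higher), and after quantile normalization 3930 were higher and 4990 lower (44.1% higher).

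Among the 12 largest rises, S100a8, an alarmin of myeloid cells, reached 208 ± 143 FPKM with BAC against 0.203 ± 0.103 FPKM with PBS (log2 change 7.23, SE 0.36); without BAC 3 its BAC mean was 138 FPKM. The cytokine gene Il1b was at 83.4 ± 34.0 FPKM against 0.292 ± 0.0888 FPKM (log2 change 5.95). The neutrophil-attracting chemokine Cxcl5 was at 116 ± 44.9 FPKM against 0.784 ± 0.317 FPKM. Mmp13, a collagenase, rose by 6.89 and its inhibitor Timp1 by 6.02 on the log2 scale. Col3a1, the chain of type III collagen, was at 446 ± 66.2 FPKM against 3.90 ± 2.06 FPKM. Ltf, which encodes lactoferrin, was 60.6-fold higher. Sprr2a1 and Sprr2a2, cornified envelope precursors, rose by 6.06 and 6.67; they belong to a cluster of near-identical copies, so the split between them is uncertain. Dynap rose by 5.71. Esp6 rose by 5.86, with 1 of the 4 control libraries, PBS 3, at 16.9 FPKM and the others at or below 0.288 FPKM; without PBS 3 the rise was 6.825.

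Among the 12 largest falls, Lypd2 and Slurp1, which encode Ly6 family proteins, were at 0.804 ± 0.442 and 0.135 ± 0.0981 FPKM with BAC against 1513 ± 111 and 236 ± 14.9 FPKM with PBS. Krt12, Lypd2 and Slurp1 had log2 changes of -9.84, -9.74 and -7.71. Krt12 (ENSMUSG00000020912.4) lies on chromosome 11 from 99415666 to 99422259 in GRCm38. Slurp1 and Lypd2 lie beside each other on chromosome 15, the former from 74724318 to 74728034 and the latter from 74732247 to 74734329. Aqp5, the water channel of corneal epithelium, was at 29.0 ± 8.59 FPKM against 1500.4 ± 175 FPKM, 51.7-fold lower. The desmosomal cadherin gene Dsg1a fell by 5.84 and the uroplakin gene Upk1b also by 5.84 on the log2 scale. Ppp1r3c, a glycogen-targeting phosphatase subunit, fell by 6.82. Ces1d, a carboxylesterase, fell by 5.72, Fam169a by 5.44, Fam83a by 5.40 and Mgarp by 5.09. Cyp4a12a was at 31.6 ± 5.40 FPKM with PBS and was listed at 0 in 3 of the 4 BAC libraries.

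In the list for corneal epithelium, 19 of 24 members were lower and 3 higher (camera with a preset correlation, adjusted p = 1.39e-08; adjusted p = 0.362 with an estimated correlation). Tkt, a transketolase abundant in this tissue, fell from 569 ± 44.8 to 55.0 ± 5.70 FPKM. Krt5, Krt14, Pax6 and Aldh3a1 were chosen after their values were seen. Aldh3a1, the corneal aldehyde dehydrogenase, was 17.8-fold lower, and Pax6, the eye-field transcription factor, was 2.86-fold lower. Of the basal keratin pair, Krt5 fell from 5557 ± 276 to 2031 ± 224 FPKM, while Krt14 rose from 229 ± 29.1 to 2510 ± 331 FPKM.

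Of 16 genes in the list for conjunctival and mucin-producing epithelium 9 were measured, with 8 higher and 1 lower. The others were not among the genes tested, so the counts say nothing of them. Krt8, Krt7 and Krt19, keratins of simple epithelia, rose by 4.63, 2.82 and 2.28 on the log2 scale, and Fcgbp, a mucus protein, fell by 1.99. The list as a whole missed the threshold (camera, adjusted p = 0.0513; 0.362 with an estimated correlation), and passed with any library but BAC 2 left out, at 0.0328 to 0.0479. It also passed with a pseudocount of 0.1 (0.0471), a filter at a mean of 2 (0.0321), array weights (0.0466), a block for replicate number (0.0226), rescaling to a common total (0.0482), median-of-ratios scaling (0.0141) and quantile normalization (0.00206). Of 21 measured genes for cornified envelope and epidermal keratinization, 13 were higher and 3 lower, or 13 and 6 after median-of-ratios scaling (camera, adjusted p = 0.0696). The list passed without BAC 2 (0.0436) or PBS 1 (0.0321), with a filter at a mean of 2 (0.0236), after median-of-ratios scaling (0.015) and after quantile normalization (0.00229). Krt17, a stress-induced keratin, was 37.6-fold higher and Sprr1a 39.6-fold higher. Of 19 genes for membrane mucins and tight junctions, 14 were lower and 4 higher (camera, adjusted p = 6.89e-05; adjusted p = 0.362 with an estimated correlation). The junction genes Cgn and F11r fell by 1.72 and 0.93, whereas Cldn8 rose by 1.86.

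**Figure D1:**
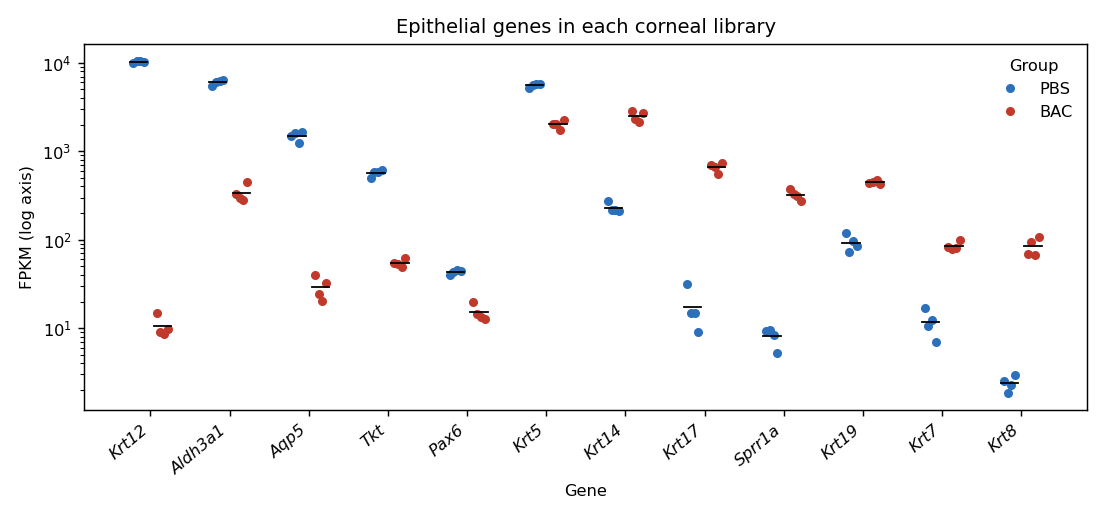
FPKM on a log axis for 12 epithelial genes in each of the 4 PBS and 4 BAC libraries; points are libraries and black lines are group means. The groups do not overlap for any of the 12 genes, with Krt12 at 10325 FPKM against 10.5 FPKM and Krt14 at 229 FPKM against 2510 FPKM.

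Transcripts of leukocytes and of innate inflammation were higher with BAC. In the neutrophil list 19 of 20 members rose (camera, adjusted p = 2.58e-05, or 0.474 with an estimated correlation). The list mean was 0.934 log2 with PBS against 4.557 with BAC. Members nearly absent with PBS, such as Csf3r and Mmp9, were kept by the filters only through their BAC values, which weakens this count. Csf3r, the receptor of the granulocyte growth factor, was at 27.6 ± 7.81 FPKM with BAC against 0.0394 ± 0.0456 FPKM with PBS (0.0255 without PBS 3). The neutrophil gelatinase gene Mmp9 was at 35.4 ± 10.1 FPKM with BAC and was listed at 0 in 3 of the 4 PBS libraries. In the list for monocytes, macrophages and dendritic cells 18 of 20 rows rose (camera, adjusted p = 1.16e-05; adjusted p = 0.362 with an estimated correlation). Lyz2, Csf1r and Adgre1 were 52.1-fold, 22.2-fold and 46.0-fold higher. The other 2 rows of that list both carried the symbol Itgam. Of 22 genes in the list for lymphocytes and natural killer cells 8 were measured. Of these 7 rose, Thy1 by 4.41 and Cd4 by 1.501, and after quantile normalization 7 rose and 1 fell (camera, adjusted p = 0.0138, or 0.362 with an estimated correlation). The list mean was 0.214 log2 with PBS against 1.785 with BAC. Members this low with PBS were kept by the filters mainly through their BAC values, so the count of rises is weak evidence. The same limit holds for low members of other lists, among them Adgre1, C3ar1, Ccl7 and Mmp13. Thy1 is also expressed by fibroblasts.

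Of 23 measured cytokines and chemokines of innate inflammation, 20 rose and 1 fell (camera, adjusted p = 4.13e-05; adjusted p = 0.362 with an estimated correlation). The alarmin cytokine Il33 was at 90.8 ± 4.87 FPKM against 3.30 ± 0.595 FPKM, and the monocyte-attracting chemokine Ccl7 at 13.96 ± 2.38 FPKM against 0.0942 ± 0.121 FPKM (0.0409 without PBS 2). In the complement list 14 of 15 members rose, C1qb by 4.39 and C3ar1 by 3.37 (camera, adjusted p = 0.000154; adjusted p = 0.362 with an estimated correlation). For antigen presentation by MHC class II, 9 of 10 members rose, H2-Aa 8.26-fold and H2-Ab1 7.72-fold (camera, adjusted p = 0.0027; adjusted p = 0.362 with an estimated correlation). Antimicrobial and alarmin genes went both ways, with 8 of 13 higher and 5 lower (camera, adjusted p = 0.551). Saa3, an acute-phase protein gene, rose by 5.57. Among 5 mast cell genes, 4 were higher, with the protease gene Cma1 up 17.7-fold (27.3-fold without PBS 3), and Kit was 9.08-fold lower (camera, adjusted p = 0.542). The hemoglobin gene Hbb-bs was at 12.9 ± 4.36 FPKM against 1.37 ± 1.51 FPKM (0.705 without PBS 1). The red blood cell list had 4 of 5 members higher and 1 lower (camera, adjusted p = 0.542).

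Genes of wound matrix, vessels and the cell cycle rose in the same corneas. In the list for myofibroblasts and wound matrix 19 of 20 members rose (camera, adjusted p = 2.5e-05; adjusted p = 0.362 with an estimated correlation). The matrix protein genes Tnc and Postn were at 122 ± 16.2 and 129 ± 32.0 FPKM against 2.85 ± 0.746 and 3.42 ± 0.945 FPKM. Of 17 matrix metalloproteinases and inhibitors 16 rose, including the metalloproteinase gene Adamts1 by 3.28 (camera, adjusted p = 4.55e-05; adjusted p = 0.362 with an estimated correlation). All 17 measured genes of blood and lymphatic vessels rose, as did the endothelial genes Cdh5 by 3.84 and Plvap by 3.54 (camera, adjusted p = 3.77e-05; adjusted p = 0.362 with an estimated correlation); after quantile normalization 15 of the 17 passed. All 25 cell cycle genes rose, with the mitotic kinase genes Cdk1 and Bub1 3.08-fold and 3.01-fold higher (camera, adjusted p = 2.69e-05; adjusted p = 0.567 with an estimated correlation).

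In the stromal keratocyte list 13 of 19 members were higher and 3 lower (camera, adjusted p = 0.0863). The list passed without PBS 4 (0.0459), after median-of-ratios scaling (0.0193) and after quantile normalization (0.00272). Thbs2 and the fibrillar collagen gene Col1a1 rose by 3.02 and 2.08. Kera and Angptl7, chosen after their values were seen, were lower, at 42.0 ± 16.3 and 46.2 ± 30.8 FPKM with BAC against 149 ± 49.0 and 172 ± 72.6 FPKM with PBS; keratocan, the product of Kera, is a proteoglycan of the corneal stroma. Of 13 corneal endothelium genes 5 were higher, among them Col8a1 by 2.39, and 1 lower, or 4 and 3 with a median of -0.00 log2 after quantile normalization (camera, adjusted p = 0.950).

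The series title names Tfam, mitochondrial dysfunction and the AIM2 inflammasome, and these genes were read out in whole corneas. Aim2, the cytosolic DNA sensor, was at 2.82 ± 0.493 FPKM with BAC against 0.0636 ± 0.0645 FPKM with PBS, or 0.0357 without PBS 4 (log2 change 1.84, SE 0.11, limma adjusted p = 5.51e-07). Nearly absent with PBS, Aim2 was kept by the filter only through its BAC values, so its direction was fixed beforehand. Tfam, the packaging and transcription factor of mtDNA, was at 8.04 ± 0.810 FPKM with BAC against 6.77 ± 0.920 FPKM with PBS and did not pass (log2 change 0.22, SE 0.10, limma adjusted p = 0.0804). Tfam lay 0.03 log2 above the median shift of all genes, and after quantile normalization its change was -0.01. It passed without PBS 4, at 0.29 (limma adjusted p = 0.0324), and with a block for replicate number, at 0.22 (limma adjusted p = 0.0475). The labels state no pairing of samples by replicate number. The share of summed FPKM from the 13 mtDNA-encoded mRNAs was 8.74% ± 0.524 with BAC and 5.14% ± 0.423 with PBS (SD, n = 4), a difference of 3.60 points (exact permutation test, two-sided, p = 0.0286, the smallest that 70 assignments allow). With samples paired by replicate number the exact permutation p was 0.125, the smallest that 4 pairs allow. In GRCm38, Aim2 (ENSMUSG00000037860.15) lies on chromosome 1 from 173350879 to 173466040 and Tfam (ENSMUSG00000003923.14) on chromosome 10 from 71225464 to 71238280.

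All 13 mtDNA-encoded mRNAs were higher, and 12 of the 13 after median-of-ratios scaling (camera, adjusted p = 0.00183; adjusted p = 0.539 with an estimated correlation). Their median change lay 0.64 log2 above that of all genes. Mt-Co1, mt-Nd5, mt-Co3 and mt-Nd3, which encode respiratory chain subunits, were 2.13-fold, 1.92-fold, 1.85-fold and 1.84-fold higher. Of 38 nuclear-encoded subunits of complexes II to V, 29 were higher and none lower (camera, adjusted p = 0.00128; adjusted p = 0.454 with an estimated correlation), and 25 were higher and 4 lower after median-of-ratios scaling. Their median change lay 0.33 log2 above that of all genes; Sdhc and Cox5b were 2.28-fold and 1.90-fold higher. Of 36 nuclear-encoded complex I subunits 23 were higher, among them Ndufc2 1.72-fold, but after median-of-ratios scaling 15 were higher and 6 lower (camera, adjusted p = 0.0675). That list passed without BAC 2 (0.0436) or PBS 1 (0.028), with a filter at a mean of 2 (0.0325), after rescaling to a common total (0.0482) and after quantile normalization (0.00713), and its median lay 0.18 log2 above that of all genes. Of 19 tricarboxylic acid cycle enzymes 14 were higher and 1 lower, or 10 and 4 after median-of-ratios scaling and 11 and 3 after quantile normalization, with Idh2 2.04-fold higher and a median 0.26 log2 above that of all genes (camera, adjusted p = 0.085, or 0.0127 after quantile normalization). Of 17 glycolysis genes 14 were higher and 1 lower (camera, adjusted p = 0.0012; adjusted p = 0.362 with an estimated correlation). Pgk1, a glycolytic kinase gene, was 2.71-fold higher, and Slc16a3, a lactate exporter, was at 6.09 ± 1.595 FPKM against 0.135 ± 0.125 FPKM (0.0727 without PBS 1).

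Genes that maintain mtDNA went both ways. Of 24 genes for mtDNA maintenance and transcription 10 were higher and 4 lower (camera, adjusted p = 0.950), and after quantile normalization 3 were higher and 10 lower. Endog rose 2.36-fold and Dguok, a mitochondrial nucleoside kinase, fell 1.85-fold; Ssbp1 rose 1.503-fold but did not pass after quantile normalization. Of 11 mitochondrial biogenesis regulators 5 were higher and 2 lower, turning to 2 higher and 4 lower after quantile normalization (camera, adjusted p = 0.943). The AMP-activated kinase subunit genes Prkaa1 and Prkaa2 moved apart, by 0.57 and -0.94 log2 relative to the median of all genes. Of 16 genes for mitochondrial dynamics and mitophagy 5 were higher and 5 lower, or 3 and 7 after median-of-ratios scaling (camera, adjusted p = 0.495). Bnip3, a mitophagy receptor, was 4.79-fold higher and the fusion gene Mfn2 1.57-fold lower.

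**Figure D2:**
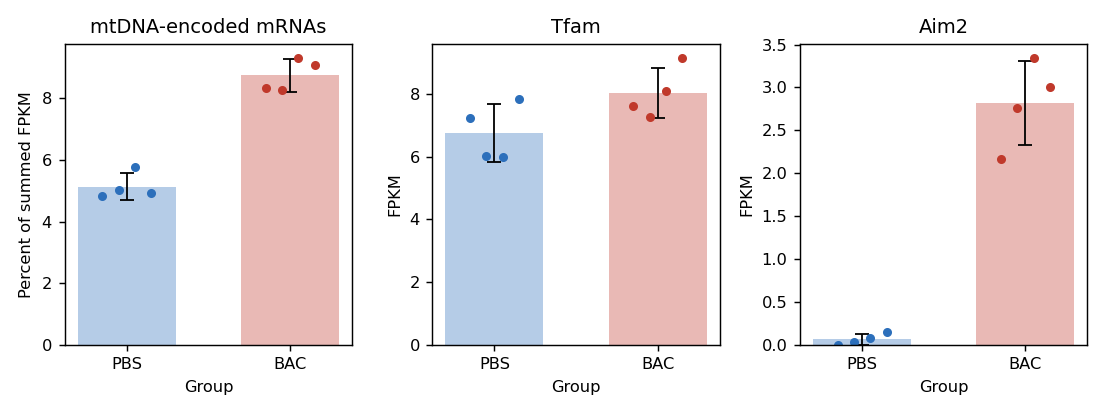
Percent of summed FPKM from the 13 mtDNA-encoded mRNAs, and FPKM of Tfam and Aim2, in the PBS and BAC groups; bars are group means, error bars SD of 4 libraries and points the libraries. The share is 5.14% with PBS and 8.74% with BAC, Tfam overlaps between the groups, and Aim2 is at 0.0636 FPKM with PBS and 2.82 FPKM with BAC.

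In the list for inflammasome and pyroptosis 11 of 15 measured members were higher and 3 lower, or 9 and 4 after quantile normalization (camera, adjusted p = 0.0696; 0.362 with an estimated correlation), and the list passed without BAC 1 (0.0482) or BAC 3 (0.0438), after median-of-ratios scaling (0.0183) and after quantile normalization (0.0224). The median log2 change of this list was 1.13, and leukocyte markers rose in the same samples, by a median of 3.24 in the neutrophil list and 2.87 in the list for monocytes, macrophages and dendritic cells. Casp1, the inflammatory caspase, was at 9.48 ± 1.19 FPKM with BAC against 0.379 ± 0.341 FPKM with PBS (0.219 without PBS 3). Mefv, which encodes pyrin, was at 6.75 ± 1.68 FPKM with BAC and listed at 0 in all 4 PBS libraries. Nlrp3, chosen after its values were seen, was at 4.59 ± 1.66 FPKM with BAC and listed at 0 in 3 PBS libraries. Casp1, Mefv, Nlrp3, Aim2 and Il1b were kept by the filter only through their BAC values. Their direction was thus fixed beforehand, which weakens the count of rises and the list p-values. Of 17 genes for cytosolic DNA and RNA sensing 7 were higher and 6 lower, which turned to 5 and 7 after median-of-ratios scaling (camera, adjusted p = 0.495). Tmem173, which encodes the adaptor STING, was 22.8-fold higher and Myd88 1.86-fold higher, while Irf7 was 2.59-fold lower.

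Interferon-stimulated genes went the other way from the cytokines. Of 27 measured, 15 were lower and 4 higher (camera, adjusted p = 0.000688; adjusted p = 0.539 with an estimated correlation). Isg15 was 4.56-fold lower and Oasl1 5.15-fold lower, while the GTPase gene Iigp1 was 4.74-fold higher. Circadian clock genes also fell more often than they rose, 9 against 2 of 18 (camera, adjusted p = 0.00394; adjusted p = 0.362 with an estimated correlation). Arntl, a core clock activator, was 3.33-fold lower, Hlf 5.27-fold lower, and Nfil3 9.27-fold higher. Times of tissue collection are not given by the labels.

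Stress and cell death genes were mixed. Of 27 genes for NRF2 and antioxidant defence 16 were higher and 5 lower, or 15 and 8 after median-of-ratios scaling (camera, adjusted p = 0.4998, or 0.0343 after quantile normalization). Hmox1, which encodes heme oxygenase, was 29.8-fold and Gpx2 81.4-fold higher, while Gsta4, a glutathione transferase gene, fell from 3305 ± 236 to 568.5 ± 47.3 FPKM. Of 20 genes for cell death other than pyroptosis 15 were higher and 2 lower, or 13 and 4 after median-of-ratios scaling and 12 and 4 after quantile normalization, among them Mlkl 5.88-fold higher (camera, adjusted p = 0.105, or 0.014 after quantile normalization). Of 19 immediate-early genes 10 were higher and 5 lower, with Fosl1 up by 2.26 and Hspa1a down 2.74-fold (camera, adjusted p = 0.950).

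Lists for lens, melanocytes and iris pigment, lacrimal and Harderian gland, sensory nerve and RNA quality did not pass on the FPKM as deposited. Of 12 lens genes none passed (camera, adjusted p = 0.091, or 0.0459 without PBS 3). PBS 1 alone held high levels of lens crystallin transcripts, with Cryaa (chosen after its values were seen) at 10.96 FPKM there and at or below 0.382 FPKM in the other PBS libraries. Of 7 melanocyte and iris genes 1 was higher, Mitf by 1.27, and 1 was lower after quantile normalization (camera, adjusted p = 0.827). Replicate 4 was highest for this list in both groups, with a mean of 3.68 log2 in BAC 4 against 1.45 to 1.87 in the other BAC libraries and 2.63 in PBS 4 against 0.619 to 0.853 in the other PBS libraries. Of 5 lacrimal and Harderian gland genes 1 was higher, Soat1 by 1.93, and 1 was lower after quantile normalization (camera, adjusted p = 0.950). PBS 3 had a list mean of 3.76 log2 against at most 0.546 in the other PBS libraries; without it, with the same genes, the list turned upward and did not pass (0.512). Of 14 sensory nerve and Schwann cell genes 4 were higher and 3 lower, or 2 and 4 after quantile normalization, with Tubb3 up by 2.17 and Mbp 1.71-fold lower (camera, adjusted p = 0.950). Of 30 ribosomal protein genes 11 were higher and 3 lower, and after median-of-ratios scaling 2 were higher and 12 lower (camera, adjusted p = 0.950). After quantile normalization 17 were higher and 1 lower, and the list passed upward (0.00642); Rps2 was 1.52-fold higher. Of 6 histone genes 5 were higher and 1 lower, or 2 and 2 after quantile normalization, with Hist1h2bc 1.77-fold higher (camera, adjusted p = 0.495). The remaining 3 lists had fewer than 5 measured members and were not tested. For T helper cytokines Gata3 rose by 1.01 and the other measured gene fell by at least 1 log2. For retina Rom1 rose by 0.64, which did not pass after quantile normalization. For skeletal muscle Acta1 rose by 2.27 and Tnni2 was 2.38-fold lower.

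Of the 40 lists tested, 17 passed the preset correlation, 13 higher and 4 lower, and none passed with an estimated correlation, where the lowest adjusted p was 0.362. Counts of members adjusted over the list alone were the same in 37 of the 43 lists and differed by 1 per direction in the other 6. The median of members and the camera direction differed in sign for mtDNA maintenance, mitochondrial dynamics, DNA and RNA sensing, and sensory nerve, all with positive medians and a direction below that of other genes. For the lacrimal list the median was -0.00 and the mean 0.27.

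**Figure D3:**
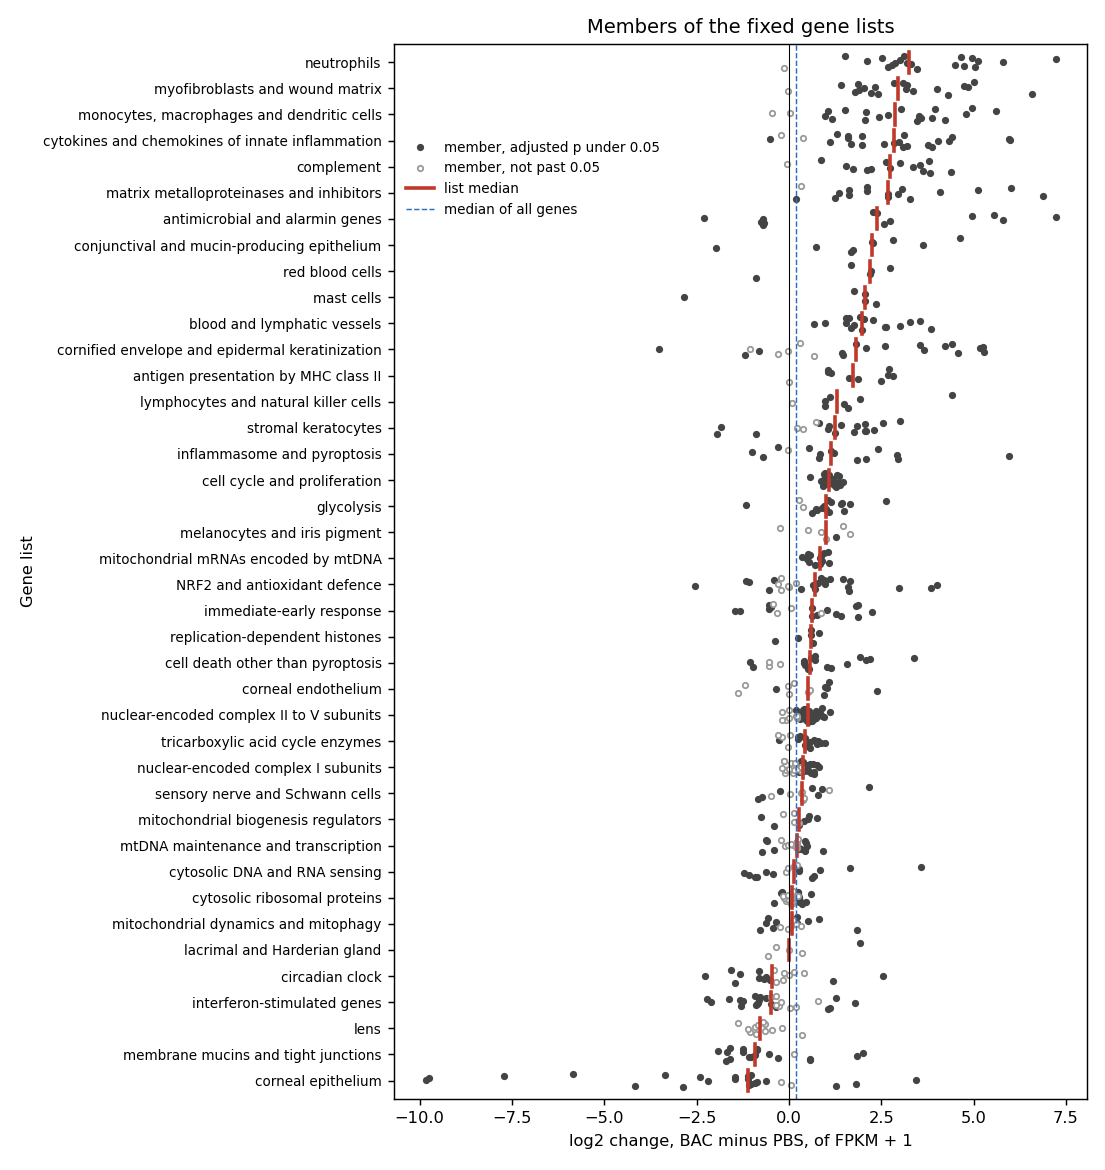
The log2 change (BAC minus PBS, of FPKM + 1) of each member of the 40 tested gene lists; filled points passed an adjusted p of 0.05, red lines are list medians and the dashed line is the median of all genes at 0.19. Neutrophil, wound matrix and macrophage lists lie highest and the corneal epithelium list lowest.

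At transcript level, where a gene's isoforms were tested apart, 8080 of 23349 transcripts passed, 5362 higher and 2718 lower. Of 5727 genes with more than 1 tested transcript, 109 had at least 1 transcript higher and 1 lower. Plac8 and Cd44, chosen after their values were seen, are examples. Plac8-201 rose from 14.6 ± 5.58 to 106 ± 15.5 FPKM while Plac8-202 fell from 108 ± 9.41 to 0.955 ± 0.522 FPKM. Cd44, a hyaluronan receptor gene, had Cd44-201 at 41.0 ± 3.19 FPKM with BAC against 84.9 ± 4.09 FPKM with PBS and Cd44-203 at 8.59 ± 3.54 against 1.07 ± 0.395 FPKM. Isoform values rest on how the authors' software divided reads among transcripts that share exons.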

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

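The tests on Krt12, the mtDNA share, neutrophils and other splits of the samples were chosen only after the results were seen; the bound for platelets was set before, and the comparison with its spread was added after.

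The first pattern is the near-loss of Krt12, Lypd2 and Slurp1. The median log2 change of 12 genes shared by surface epithelia, all expressed in the control corneas, was -0.85, with 9 lower, 2 higher and a range from -2.50 to 3.45, which argues against a loss of epithelial cells as the whole cause. The median of 5 genes restricted to corneal stroma and endothelium was -1.19, of which 2 were lower and 3 did not pass. These values argue against other tissue in place of the whole cornea. Such genes cannot show whether the epithelium alone, or a part of the tissue, came from beside the cornea. Across all genes, libraries of 1 group correlated at 0.976 or above and libraries of different groups at 0.824 or below, which argues against exchanged single libraries; an exchange of whole groups was not tested. A change of epithelial identity or differentiation with BAC may remain, and the design cannot say in which cells.

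The second pattern is the higher share of mtDNA-encoded mRNAs. With the 10 most abundant other genes left out of the total the difference was 3.27 points (exact permutation p = 0.0286), against 3.60 with them, so loss of Krt12 and a few other abundant transcripts from the total could not account for it. A factor common to all genes of a library cancels in the share, so median-of-ratios scaling cannot test it. For the single mRNAs, 12 of the 13 stayed higher after that scaling, which argues against the general shift as the whole cause of their rises. A change in mitochondrial transcripts per cell, or in the mix of cells, stays open as an untested biological explanation.

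The third pattern is Ppbp, at 1213 FPKM with BAC. Ppbp, also known as a platelet product, had a mean 14.4 times that of Pf4, between 10.7 and 22.0 in each BAC library, above the bound of 10 set for platelets, but by less than the SD of the ratio over libraries (4.90), so platelets stay open. Of 5 measured platelet markers 3 rose and 2 fell (median log2 change 1.58, highest 5.63 for Pf4), the latter being Itga2b and Gp1bb, at 0.719 ± 0.101 and 0.429 ± 0.243 FPKM with BAC against 1.46 ± 0.134 and 2.76 ± 0.308 FPKM with PBS; the other 8 of 13 were not among the genes tested. Ppbp varied 1.35-fold over the BAC libraries and the 19 neutrophil markers that rose varied 1.53-fold to 10.5-fold (median 2.69), but the nearest is too close over 4 libraries to exclude neutrophils, which stay open. Expression in cells of the cornea itself may also remain, which these data do not test.

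Only the real split of the 8 samples gave as many genes (8771, 1 of 35 splits) or transcripts (8080, 1 of 35). The other splits gave at most 2 genes and 11 transcripts. Each of these has BAC and PBS libraries on both sides, so a strong group difference widens their spread and keeps their counts low. The comparison can give no less than 1 of 35, and it cannot exclude a difference in handling that follows the groups. For gene lists, 14 of 35 splits gave 17 or more lists and the highest other gave 21. Statements on lists therefore rest on their members.

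In 336 groups of 4 libraries, 25 had an end value far from the others, where chance marks about 16.8. PBS 1 stood apart for lens genes, with Crygs at 31.8 FPKM against at most 0.619 in the other PBS libraries, Cryaa at 10.96 FPKM and a lens list mean of 3.196 on the log2 scale. PBS 3 stood apart for the lacrimal and Harderian gland list (mean 3.76 log2, next 0.546), Esp6 (16.9 FPKM), mt-Co1 (2275 FPKM), the mtDNA mRNA list (mean 9.69 log2, next 9.50) and Clec4d, listed at 0. PBS 4 stood apart for the melanocyte and iris list (mean 2.63 log2, next 0.853), for which BAC 4 was also highest of its group (3.68, next 1.87), and Mmp9 (0.0808 FPKM, the others at 0). PBS 1 was also apart for Krt14 (272 FPKM), Irf7 (9.65 FPKM), Slc16a3 (0.322 FPKM) and Acta1 (0.104 FPKM), and PBS 2 for Nlrp3 (0.0247 FPKM, the others at 0). Among BAC libraries, BAC 3 was highest for Cxcl5 (183 FPKM), Thy1 (40.4 FPKM), mt-Co3 (2204 FPKM), Hmox1 (54.4 FPKM) and Soat1 (7.13 FPKM). BAC 4 was apart for Angptl7 (92.4 FPKM, next 31.7), Cdk1 (19.2 FPKM) and Mgarp (13.1 FPKM, the lowest). Crygs was at 0.283 FPKM in BAC 1 and Cyp4a12a at 0.0403 FPKM in BAC 2, each listed at 0 in the other BAC libraries.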

How the results depend on the processing

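With each library left out in turn, 8287 to 8541 genes, 5480 to 5771 higher and 2701 to 2828 lower genes, 7081 to 7444 transcripts and 18 to 20 lists passed, and the difference in mtDNA mRNA share was 3.42 to 3.81 points. After quantile normalization 4990 genes were lower and 26 lists passed, and 87 of the gene calls changed direction; the cause was not tested. With an estimated correlation 0 lists passed; the cause was not tested. Asking for a log2 change of at least 1 left 2956 genes, 2134 higher and 822 lower, and 4214 transcripts, by its construction. Tfam was at -0.0142 log2 after quantile normalization, and it passed without PBS 4 (0.29) and with the replicate block (0.22, limma adjusted p = 0.0475); over all alternatives its adjusted p ran from 0.0324 to 0.906. Replicate numbers were not taken to pair the samples, since not every correlation of same-numbered samples was above 0.1. The correlations of same-numbered deviations were 0.0527, 0.109, 0.121 and 0.114, and BAC 2, 3 and 4 correlated best with their own number while BAC 1 correlated best with PBS 2 (0.104). The second principal component also fell with the number in both groups, from 11.4 to -21.4 for BAC and from 9.63 to -13.2 for PBS, so pairing is not excluded. With the replicate block, 8519 genes, 6819 transcripts and 18 lists passed, the conjunctival list among them (0.0226), and the share differed by 3.60 points with an exact p of 0.125, the smallest that 4 pairs allow.

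Lists that had missed the threshold turned direction under some settings, with these adjusted p (camera); ranges with a library left out are over all 8 libraries, whether or not the direction turned, and the libraries that turned it are named. The values were lacrimal 0.986 with a pseudocount of 0.1, 0.760 after median-of-ratios scaling and 0.722 after quantile normalization, and 0.512 to 0.962 with a library left out (turned by PBS 3); mtDNA maintenance 0.979 with a filter at 2, 0.980 with the replicate block, and 0.889 to 0.990 with a library left out (turned by BAC 1 and PBS 4). Immediate-early genes had 0.934 with the filter at 2 and 0.889 to 0.985 with a library left out (turned by BAC 2 and PBS 4). Sensory nerve had 0.803 after median-of-ratios scaling, 0.980 with the block, and 0.804 to 0.985 with a library left out (turned by BAC 1 and BAC 3). Ribosomal proteins had 0.106 after median-of-ratios scaling and 0.578 to 0.985 with a library left out (turned by BAC 3, PBS 2 and PBS 3). Biogenesis regulators had 0.752 after quantile normalization and corneal endothelium 0.374 to 0.980 with a library left out (turned by PBS 4); causes were not tested. The lacrimal list without PBS 3 (0.512), the lens list without PBS 1 (0.396) and the histone list without BAC 3 (0.524) fell under 5 members by the filter, so they were tested on the genes kept with all 8 libraries, an alternative chosen after seeing the data. Under 36 combinations of a list and a setting, lists that had missed the threshold passed in the same direction. No other alternative gave a gene or transcript count more than 1.5 times away. The planned share over all mtDNA genes gave no other value, since the table held the same 13, and depth limits could not be set.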

Other observations

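Ppbp lies in a cluster of CXC chemokine genes on chromosome 5 (GRCm38), and every tested gene of that cluster rose with BAC. All but Cxcl1 had a mean at or below 0.784 FPKM with PBS, so a near-complete loss would have removed them by the filter. That all rose is therefore weak evidence. From Cxcl5, which starts at 90759360, to Cxcl2, which ends at 90905938, the table held Cxcl5, Ppbp, Pf4, Cxcl3, Cxcl1 and Cxcl2, which were read out after Ppbp was seen. Pf4 was at 84.3 ± 26.5 FPKM with BAC against 0.676 ± 0.269 FPKM with PBS. Cxcl3 was at 20.02 ± 6.45 FPKM against 0.0139 ± 0.0161 FPKM (0.00924 without PBS 3), Cxcl1 at 13.9 ± 3.33 against 1.11 ± 0.626 FPKM, and Cxcl2 at 27.5 ± 13.9 against 0.603 ± 0.398 FPKM. Of the nearest tested genes outside the cluster, Rassf6 had a log2 change of -0.27 (limma adjusted p = 0.0161) and Mthfd2l 0.07 (adjusted p = 0.516). Beyond Mthfd2l, Epgn and Areg rose by 0.71 and 1.27 (limma adjusted p = 0.00012 and 5.47e-05). Ereg did not pass, at -0.36 (limma adjusted p = 0.0744). Epcam, a membrane protein of epithelial cells also picked after its value was seen, rose 2.40-fold in the corneas that lost Krt12. Most genes shared by surface epithelia went the other way, with 9 of 12 lower and 2 higher (median log2 change -0.85).

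Itgam, the integrin chain of neutrophils and macrophages, did not pass on either of its 2 rows (limma adjusted p = 0.959 and 0.623), although most other markers of these cells rose. The rows overlap on chromosome 7, from 128062640 to 128118491 and from 128062683 to 128128160, and their values trade off between libraries: PBS 1 had 36.1 and 2.33 FPKM where PBS 2 had 7.57 and 34.1 FPKM. Their sum was 29.1 ± 2.53 FPKM with BAC and 35.5 ± 5.62 FPKM with PBS.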
